A study of Homo sapiens with 60 samples.

How the data were processed

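The study's own processing, as its labels give it, used FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 with the human genome build hg38 (GRCh38). The annotation release behind it is not given in the sources used here. The deposited values were RSEM expected counts per gene, which the authors had made by aligning trimmed reads with STAR and estimating counts per gene with RSEM. Directional mRNA libraries had been sequenced on an MGI instrument as paired-end reads. The table held 60675 Ensembl genes and 279 columns, of which 60 belonged to the samples described here and 219 were not used here. The expected counts were rounded, and 90.67% were whole already. Symbols came from an Ensembl name table (56558 genes) and positions from GENCODE release 29 on GRCh38 (57055 genes found). The vehicle concentration is given here as the sample labels state it, and the series description states another one.

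Genes were filtered with filterByExpr on the groups, which left 17516 genes, and libraries were scaled with TMM factors of 0.936 to 1.028. All 19 groups with at least 2 libraries (54 libraries) were fitted together with the edgeR quasi-likelihood method (estimateDisp, glmQLFit with its robust option, glmQLFTest), with a coefficient for each group, 35 residual degrees of freedom and a biological coefficient of variation of 0.095. The Benjamini-Hochberg method adjusted p within each of the 18 comparisons with vehicle, 6 of high with low dose, 3 between extracts and 3 tests of a difference between dose effects. The comparisons and their tests, the lists, the rule for naming genes and all but 2 of the alternatives were fixed before the data were examined, and the alternatives and tests chosen later are named as such where they are given. The dispersion step was first run with its robust option and then with its default settings to save time, after counts from the first run had been seen. The results with either are compared under the dependence on processing. The fit used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and plots used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. CPM values were scaled with the TMM factors.

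The genes named were those with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group, every library of one group above every library of the other, and a symbol that is not a clone or locus name. Among these were taken the 10 largest log2 fold changes in each direction for the high dose against vehicle, 3 for the medium and low doses, 5 for high against low and for pairs of extracts, and the 3 smallest p of each test between dose effects. For each list discussed, the 4 called members with the largest changes and a mean of at least 1 CPM could be named too. The report gives a part of these, with the function known of each. 38 lists (31 of pathways and 7 of cell type markers, 698 genes, 697 of them found in the table) were tested with camera at a preset correlation of 0.01, with adjustment over all lists and comparisons of a family. Each test was repeated with a correlation estimated from the data. Groups with 1 library were compared with the vehicle mean as log2 ratios of CPM + 1 without a test.

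In a self-test, changes of known size were put into simulated counts for 50 genes at each size. For 3 libraries against 3, edgeR called 30% of genes changed 1.25-fold, 66% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, with 6 false calls among 17516 genes. DESeq2 called 70%, 96% and 100%, with 25 false calls. For 2 libraries against 3, edgeR called 32%, 64%, 92% and 100%, with 9 false calls. The list test found the NRF2 targets changed in the simulation (adjusted p = 3.45e-54) and called 4 of the other lists, 1 of which shared genes with it. The replicate numbers might pair libraries, so 30 comparisons were checked for a correlation of deviations within numbered pairs, which ran from -0.23 to 0.56. Only for Astragalus high against low did all pairs exceed 0.1, at 0.13 to 0.27, and 56 genes were called with a replicate term and 53 with it within the set, against 49. In the Cinnamon and Astragalus set, replicate 1 deviated from its group with GC content. Spearman's rho was 0.35 to 0.56 in all its groups but Astragalus low (0.00). The main fit had no term for such a shared deviation. Between 51 pairs of replicates the median ratio of scatter ran from 0.61 to 32.22 with a median of 0.97, where counting noise alone gives 0.45, so none of these replicates was a copy of another.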

Results

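RNA was sequenced from SW1783 cells, an established human astrocytoma line, kept for 24 h with a water extract of a medicinal plant or of a plant formula, or with 0.1% DMSO as the vehicle. The preparations were Cnidium rhizome, prepared Rehmannia root, Cinnamon bark, Astragalus root, Angelica root, Paeonia root and the formulas Sagunja-tang and Samul-tang. Each was given at 500 µg/mL, 100 µg/mL and 20 µg/mL, called the high, medium and low dose here. The stated aim was to describe tonifying herbal preparations by the transcript changes they bring about. There were 60 libraries in 25 groups: 3 vehicle libraries, 3 libraries at each dose of Cnidium, Rehmannia, Cinnamon, Astragalus and Sagunja, 2 at each dose of Samul, and 1 at each dose of Angelica and Paeonia. Total expected counts per library ran from 20604792 to 29609799, and 22705 to 23990 genes had a count.

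Changes are log2 fold changes ± standard error, with n = 3 libraries per group unless n = 2 is stated. The standard error was derived from the F statistic, with a spread estimated over all groups in the fit. It is not the scatter of the compared libraries alone. Levels are CPM, counts scaled to the library total and the TMM factors, as mean ± SD. Genes were called at an adjusted p under 0.05 among 17516 genes. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these samples only. All sample titles name batch B. The sets were read from the first part of the sample codes, in which the vehicle libraries differ from the extract libraries. The labels give a DMSO level for the vehicle only. A comparison with vehicle therefore cannot by itself tell the set or the solvent from the treatment. Comparisons of the high with the low dose lie within 1 set, and they are given beside those with vehicle. 1 library, replicate 1 of Sagunja low, lay far from its replicates and widened the pooled spread. Without it nearly all counts were higher.

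The Cinnamon comparison asked what Cinnamon bark extract does to these cells. HMOX1 (ENSG00000100292, chromosome 22, 35380361 to 35394214), which encodes the heme-degrading enzyme heme oxygenase 1, rose 17.7-fold at the high dose, from 79.0 ± 2.21 to 1400 ± 63.7 CPM (4.15 ± 0.09, adjusted p = 8.41e-32). The iron storage genes FTL (1.87 ± 0.10, adjusted p = 7.07e-19) and FTH1 (1.76 ± 0.10, adjusted p = 3.25e-17) rose with it, and so did AKR1C1, a reductase gene driven by the oxidant sensor NRF2 (2.38 ± 0.15, adjusted p = 2.13e-16). TXNIP, an inhibitor of thioredoxin, rose by 2.11 ± 0.10 and the stress cytokine gene GDF15 by 1.73 ± 0.13. INSIG1, a sterol-responsive regulator of cholesterol synthesis, rose from 164 ± 4.04 to 566 ± 41.0 CPM (1.78 ± 0.07, adjusted p = 1.15e-22). MT1E, a metal-binding metallothionein gene with close paralogs among which reads can be divided wrongly, fell from 24.0 to 2.18 CPM (-3.46 ± 0.15, adjusted p = 5.17e-22), and CCN2, a target of TGF-beta and YAP signalling, fell by 1.77 ± 0.12 log2 units. The kinetochore motor gene CENPE fell too (-1.89 ± 0.15, adjusted p = 8.63e-13). Its level varied widely between the Cinnamon high libraries, at 17.7 ± 7.66 CPM against 67.6 ± 4.61 CPM with Cinnamon low.

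Of 20 NRF2 targets, 19 were called higher with Cinnamon high, also 19 adjusted over the list alone, with a median of 1.01 (adjusted p = 1.77e-75). Cholesterol synthesis genes rose (20 of 22, 21 adjusted over the list alone, median 0.54, adjusted p = 1.93e-26), as did hypoxia targets (20 of 23, 21 adjusted over the list alone, median 0.45, adjusted p = 3.57e-33) and lysosomal genes (18 of 26, 19 adjusted over the list alone, median 0.34, adjusted p = 3.65e-20). The hypoxia members included NDRG1 (1.61 ± 0.07) and the glucose transporter gene SLC2A3 (1.11). Targets of TGF-beta and YAP fell (16 of 20, 18 adjusted over the list alone, median -0.58, adjusted p = 1.76e-17), and so did metallothionein and zinc export genes (6 of 7, also 6 adjusted over the list alone, median -1.41, adjusted p = 2.3e-17) and mitosis genes (16 of 26, 21 adjusted over the list alone, median -0.28, adjusted p = 6.11e-11), among them MKI67 (-1.44). AHR targets were higher in 8 of 11 and lower in 1 (9 and 1 adjusted over the list alone, median 0.47, adjusted p = 5.52e-07). ATF4 targets of the amino acid response rose (14 of 22, 15 adjusted over the list alone, adjusted p = 3.46e-08). Collagen and matrix genes were lower by the list test with a preset correlation (12 of 22, also 12 adjusted over the list alone, adjusted p = 0.000141), but adjusted p = 0.417 with an estimated correlation. The lower heat shock and S phase lists (adjusted p = 0.0241 and 0.0372) were not called either, at adjusted p = 0.18 and 0.154 with an estimated correlation. Of the 38 lists, 19 were called and 15 of these held with an estimated correlation.

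In all, 3986 genes were called between Cinnamon high and vehicle, 2072 higher and 1914 lower, and 427 of them changed at least 2-fold. Leaving out 1 library at a time gave 3062 to 3305 genes, and 6265 were called without Sagunja low library 1. The groups did not overlap in 8209 genes (46.9%, where chance gives 10%). Against the low dose of the same set the change was nearly as large, with 3781 genes called (6271 without Sagunja low library 1), HMOX1 higher by 4.10 ± 0.09 (adjusted p = 1.23e-31) and MT1E lower (-3.22 ± 0.15, adjusted p = 9.28e-21). NRF2 targets were called in the same comparison for 19 of 20 genes higher and 1 lower (adjusted p = 1.94e-70). At the medium dose HMOX1 reached 179 ± 14.4 CPM (1.18 ± 0.08, adjusted p = 8.27e-13), and the retinal reductase gene DHRS3 fell (-1.94 ± 0.15, adjusted p = 2.11e-12), among 401 called genes (197 higher, 204 lower). At the low dose DHRS3 fell by 0.74 ± 0.14 and the nuclear long noncoding RNA gene NEAT1 rose by 0.93, among 185 called genes (118 higher, 67 lower). Leaving out 1 library gave 189 (without Cinnamon medium replicate 2) to 430 (without Cinnamon medium replicate 1) genes at the medium dose, and 82 (without vehicle replicate 1) to 259 (without Cinnamon low replicate 1) at the low dose. Without Sagunja low library 1 the counts were 1297 and 952. The share of higher calls at the medium and low dose turned with the method: it was 49.1% and 63.8%, but 61.1% and 76.1% with library size alone, 39.6% and 42.4% without Sagunja low library 1, and 44.1% and 50.1% with only the groups compared in the fit, where 1170 and 453 genes were called.

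**Figure D1:**
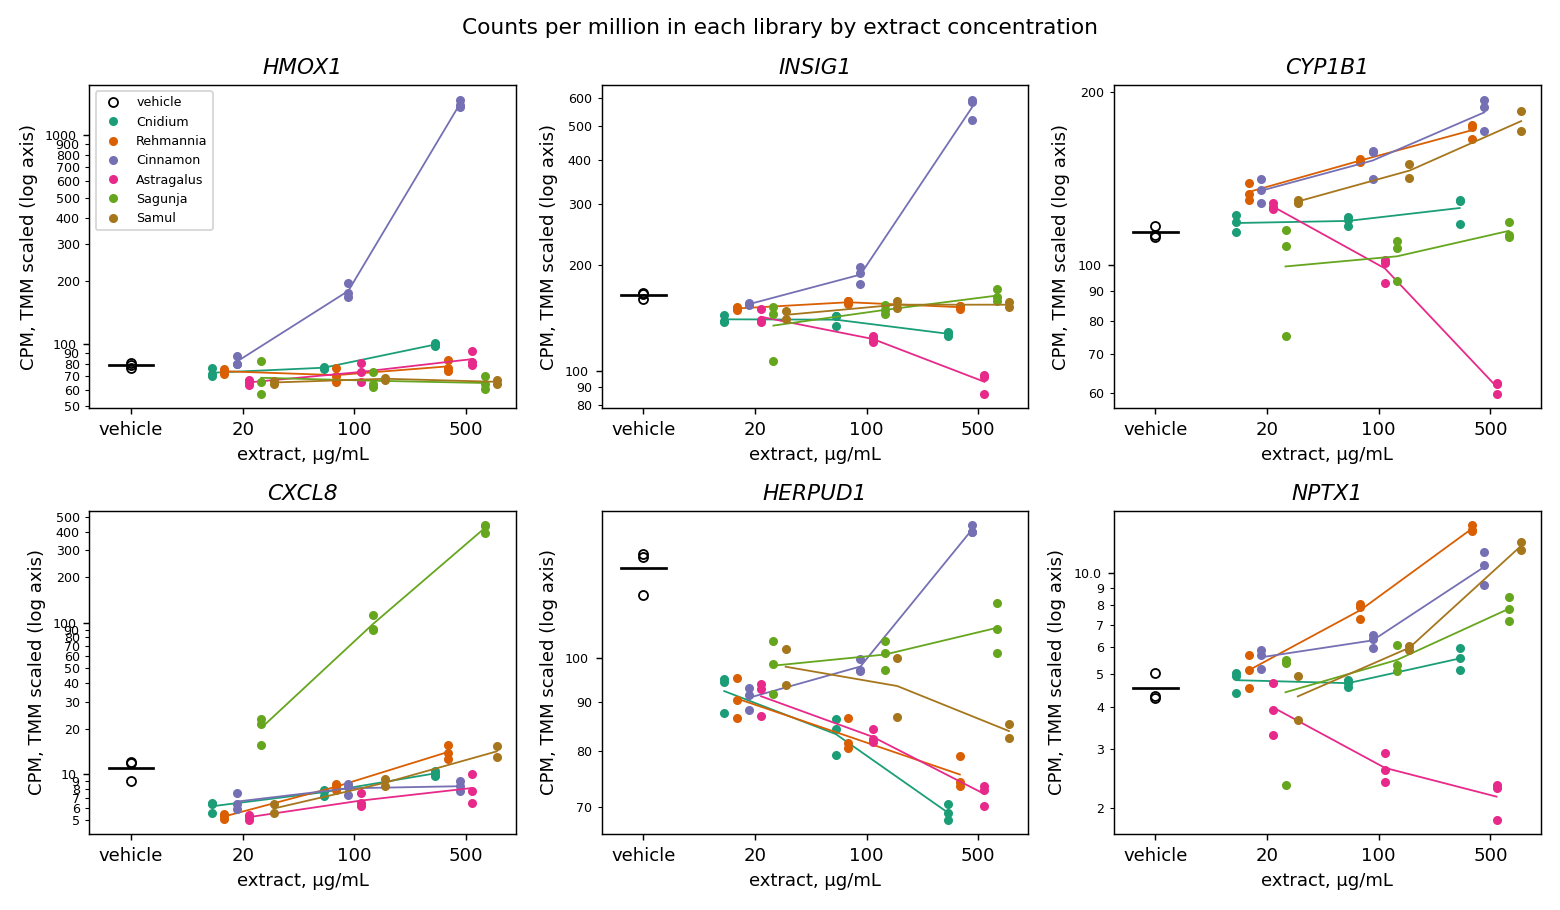
CPM on a log axis for HMOX1, INSIG1, CYP1B1, CXCL8, HERPUD1 and NPTX1 in each library (points) of the 6 replicated extracts against the dose in µg/mL, with lines joining group means and vehicle libraries as open circles. HMOX1 rose to a mean of 1400 with Cinnamon high and CXCL8 to 420 with Sagunja high, from 79.0 and 11 in vehicle.

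The Sagunja comparison asked what the Sagunja formula does. Genes of neutrophil-attracting chemokines rose at the high dose. CXCL8 (ENSG00000169429, chromosome 4, 73740506 to 73743716) rose 38.2-fold, from 11 ± 1.68 to 420 ± 27.4 CPM (5.26 ± 0.13, adjusted p = 5.34e-30), and CXCL1, which lies on the same chromosome from 73869393 to 73871242, rose from 0.262 to 17.5 CPM (6.03 ± 0.31, adjusted p = 4.35e-19). The granulocyte growth factor gene CSF3 rose by 5.72 ± 0.33, the cytokine gene IL6 by 3.13 ± 0.10 (adjusted p = 2.23e-26), IL1B by 2.59 ± 0.11 and the mitochondrial superoxide dismutase gene SOD2 by 2.63 ± 0.07 (648 against 104 CPM). The integrin gene ITGB4 fell from 20.3 to 6.21 CPM (-1.70 ± 0.11, adjusted p = 2.95e-16), and the smooth muscle actin gene ACTA2 fell from 137 to 63.2 CPM (-1.11 ± 0.09, adjusted p = 4.01e-12).

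NF-kB targets were called higher in 27 of 28 genes with Sagunja high (28 adjusted over the list alone), with a median of 2.43 (adjusted p = 1.84e-265, and 1.76e-24 with an estimated correlation). Interferon response genes rose in 20 of 26 (20 adjusted over the list alone, median 0.51, adjusted p = 7.33e-18), including the antiviral gene OAS1 (1.74 ± 0.30) and the RNA sensor gene RIGI (1.10). Fibroblast and smooth muscle markers fell in 5 of 9 (5 adjusted over the list alone, median -0.46, adjusted p = 1.67e-05), with PDGFRB at -0.73 and THY1 at -0.52. Astrocyte markers fell in 5 of 11 (5 adjusted over the list alone, median -0.23, adjusted p = 0.00309), among them CLU (-0.41) and SOX9 (-0.43), where SOX9 was at -0.20 with the low doses as the reference (adjusted p = 0.0643). The list of AHR targets was called upward (adjusted p = 0.00254) although its median was -0.01, with a mean of 0.06. Its member SERPINB2, which inflammatory signals also induce, rose by 2.49 ± 0.07, and the list was not tested without it. Collagen and matrix genes were lower in 9 of 22 and higher in 1 with a preset correlation (10 and 1 adjusted over the list alone, adjusted p = 0.00146), but adjusted p = 0.534 with an estimated correlation. Metallothionein and zinc export genes were higher (3 of 7, 6 adjusted over the list alone, adjusted p = 0.00457) and cholesterol synthesis genes lower (5 of 22, also 5 adjusted over the list alone, adjusted p = 0.0417) only with the preset value, at adjusted p = 0.1 and 0.139 with an estimated correlation. Of the 38 lists 9 were called, 6 of them with an estimated correlation too. Against the low dose of the same set the interferon list was called (13 of 26, 14 adjusted over the list alone, adjusted p = 3.93e-07), the fibroblast and smooth muscle list was called with the preset correlation (adjusted p = 0.0448, but adjusted p = 0.0704 with an estimated correlation), and the astrocyte list was not (adjusted p = 0.368).

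Between Sagunja high and vehicle 2987 genes were called (1566 higher, 1421 lower, 280 at least 2-fold). Scaling by library size alone put 63.1% of the calls on the higher side, against 52.4% with the normalization used. Without any 1 of the libraries it was 2024 to 2300, and 5400 were called without Sagunja low library 1, 49% of them higher, and 6477 with only these groups in the fit. At the medium dose CXCL8 reached 97.9 ± 13.1 CPM (3.15 ± 0.12, adjusted p = 8.96e-23), IL6 rose by 1.97 ± 0.10, and 24 of 28 NF-kB targets were called higher (26 adjusted over the list alone, median 1.39, adjusted p = 9.73e-171), among 1107 called genes. That count was 571 without vehicle replicate 1 and 996 without Sagunja medium replicate 1, and 2083 with only these groups in the fit, and 3065 without Sagunja low library 1, which brought the share of higher calls from 55.5% to 46.2%. At the low dose 16 NF-kB targets were called higher and 2 lower (19 and 2 adjusted over the list alone, median 0.59, adjusted p = 2.23e-11), among 3864 genes (2384 higher, 1480 lower). The low-dose count rested on its first library: without it 1997 genes were called, 39.5% of them higher against 61.7% with it, and 944 genes were shared. With only the 2 groups in the fit, edgeR called 0 genes, while 887 had an unadjusted p under 0.05 and DESeq2 with all groups called 4025. The count also ran to 6977 without Sagunja low replicate 3. Against the low dose of the same set CXCL8 was higher with Sagunja high (420 against 20.2 CPM, 4.37 ± 0.13, adjusted p = 7.32e-28), and all but 1 of the 28 NF-kB targets were called higher (median 1.78, adjusted p = 1.55e-198). The count of 3586 genes between these doses fell to 1133 without Sagunja low library 1, rose to 7487 without replicate 3, and was 22 with these 2 groups alone.

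**Figure D2:**
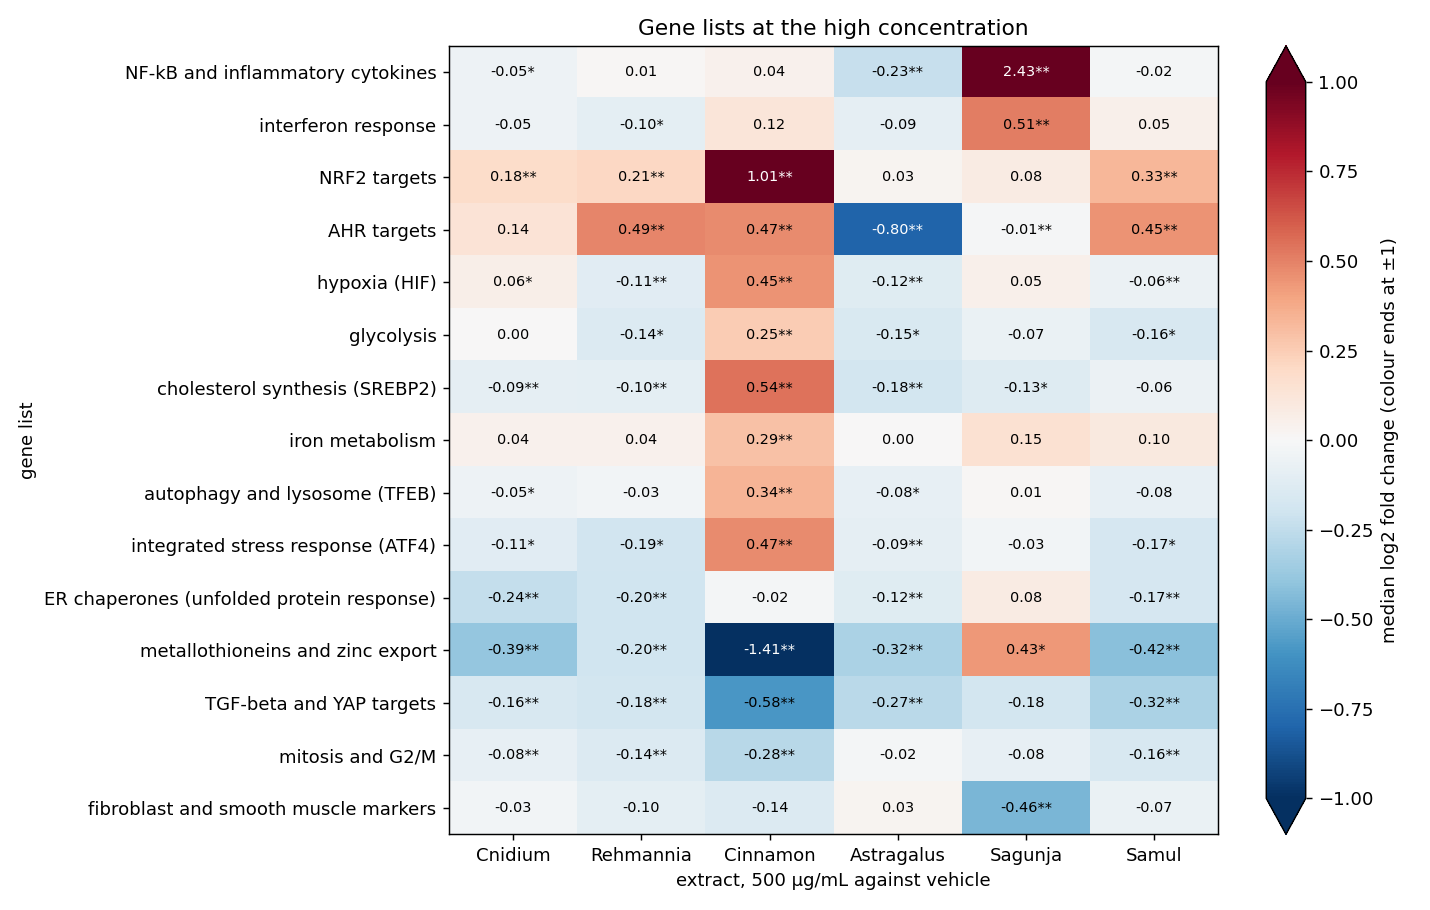
Median log2 fold change of 15 gene lists (vertical axis) in the 6 replicated extracts at the high dose against vehicle (horizontal axis), with 1 asterisk for a list called with the preset correlation and a pair of asterisks where the estimated correlation gave a call too. NF-kB targets had a median of 2.43 with Sagunja, NRF2 targets 1.01 with Cinnamon and AHR targets -0.80 with Astragalus.

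The Astragalus comparison asked what Astragalus root extract does. Targets of the aryl hydrocarbon receptor (AHR), a sensor of aromatic compounds, fell at the high dose: CYP1B1, which encodes a steroid- and toxin-oxidizing P450, went from 114 ± 2.89 to 61.4 ± 1.53 CPM (-0.89 ± 0.08, adjusted p = 2.25e-10), and the receptor's own repressor gene AHRR fell by 0.92 ± 0.10 (adjusted p = 7.4e-08). The serpin gene SERPINB2 fell from 42.6 ± 2.75 to 18.5 ± 0.871 CPM (-1.20 ± 0.07, adjusted p = 3.16e-16), the hyaluronan synthase gene HAS3 by 1.04 ± 0.13 and the chemokine gene CCL2 by 0.80 ± 0.10. INSIG1 fell to 93.1 ± 6.14 CPM (-0.82 ± 0.07, adjusted p = 4.98e-11), and the stanniocalcin gene STC2 fell from 541 to 311 CPM (-0.80 ± 0.04, adjusted p = 4.96e-17). The keratin-associated gene KRTAP2-3 fell by 1.74 ± 0.17, while the serpin gene SERPINB3 rose from 2.7 to 8.02 CPM (1.57 ± 0.13, adjusted p = 6.72e-12).

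AHR targets were lower in 6 of 11 genes with Astragalus high (6 adjusted over the list alone, median -0.80, adjusted p = 2.45e-30). TGF-beta and YAP targets fell (9 of 20, 11 adjusted over the list alone, median -0.27, adjusted p = 3.1e-12), as did cholesterol synthesis genes (3 of 22, 7 adjusted over the list alone, median -0.18, adjusted p = 2.17e-09) and NF-kB targets (10 of 28, median -0.23, adjusted p = 4e-07), of which 11 were lower and 2 higher adjusted over the list alone. The glycolysis list was lower with the preset correlation (3 of 18, 4 adjusted over the list alone, adjusted p = 6.24e-07), with adjusted p = 0.0622 with an estimated correlation. Against the low dose of the same set the lower TGF-beta and YAP list (0 of 20, median 0.00, adjusted p = 0.808) and the lower NF-kB list were not found. The latter had 2 genes called higher (3 higher and 2 lower adjusted over the list alone, median 0.02, adjusted p = 0.17). Of the 38 lists 14 were called, and 10 held. In the fit of all groups 780 genes were called at the high dose (418 higher, 362 lower), 691 at the medium (314 higher, 377 lower) and 643 at the low dose (287 higher, 356 lower), but with only the 2 groups compared in the fit the counts were 873, 3054 and 4186, and with the low-dose groups as the reference 256 were called at the high dose. Scaling by library size alone put 72.1%, 58.8% and 64.3% of the calls on the higher side, against 53.6%, 45.4% and 44.6%. With 1 library left out it was 405 (without Astragalus high replicate 2) to 920 (without Astragalus high replicate 1) genes at the high dose. The medium dose gave 278 (without vehicle replicate 1) to 534 (without Astragalus medium replicate 1), and the low dose 241 (without Astragalus low replicate 3) to 442 (without Astragalus low replicate 1). Without Sagunja low library 1 the counts were 2214, 2419 and 2467, with 42.8%, 38% and 37.3% higher, and with only the groups compared 47.3%, 39.4% and 45.6% were higher.

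Within the Astragalus set 49 genes were called between the high and the low dose (17 higher, 32 lower). CYP1B1 was lower at the high dose (61.4 against 126 CPM, -1.04 ± 0.08, adjusted p = 6.02e-12), as was AHRR (-0.74 ± 0.10, adjusted p = 3.06e-05), and AHR targets fell as a list (5 of 11, 6 adjusted over the list alone, median -0.56, adjusted p = 3.88e-37). The count was 22 without Astragalus high replicate 1 and 35 without Astragalus high replicate 3, 203 without Sagunja low library 1, and 13 with only these 2 groups in the fit. At the low dose CXCL8 fell against vehicle by 1.08 ± 0.14, the cytokine gene LIF by 0.93 ± 0.13 and KRTAP2-3 as well. The lower CXCL8 was not particular to Astragalus. Low-dose libraries of Cnidium, Rehmannia, Cinnamon, Astragalus and Samul had 5.02 to 7.49 CPM, against 9.05 to 12 in vehicle. Those of Sagunja had 15.7 to 23.3 CPM. At the medium dose NEAT1 rose by 0.92 ± 0.10 (adjusted p = 7.63e-08).

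The Rehmannia comparison asked what prepared Rehmannia root does. NPTX1, which encodes a secreted neuronal pentraxin, rose from 4.54 ± 0.447 to 13.5 ± 0.255 CPM at the high dose (1.57 ± 0.15, adjusted p = 6.8e-10), the gene of the vasoactive intestinal peptide receptor VIPR1 rose by 1.45 ± 0.12 (adjusted p = 7.54e-11), and IGFBP1, an insulin-like growth factor binding protein gene, rose from 20.5 to 46.4 CPM (1.18 ± 0.12, adjusted p = 3.04e-09). THBD, the thrombomodulin gene, rose by 0.95 ± 0.09 and TXNIP by 0.92 ± 0.10. The hypoxia-inducible mitophagy gene BNIP3 fell from 119 to 75.4 CPM (-0.66 ± 0.05, adjusted p = 5.89e-11), and the endoplasmic reticulum stress gene HERPUD1 fell by 0.71 ± 0.06 (adjusted p = 2.11e-11). HERPUD1 was at -0.44 against vehicle already at the Rehmannia low dose, and lower at the low dose of every replicated extract. It was at 73.7 to 79.1 CPM with Rehmannia high and 86.6 to 95.3 CPM with Rehmannia low. In contrast to Astragalus, 7 of 11 AHR targets were called higher (8 higher and 1 lower adjusted over the list alone, median 0.49, adjusted p = 1.39e-21), with CYP1B1 at 0.59 ± 0.08 and AHRR at 0.57 ± 0.10.

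Chaperones of the endoplasmic reticulum fell with Rehmannia high (9 of 19, 10 adjusted over the list alone, median -0.20, adjusted p = 3.95e-23), NRF2 targets rose (4 of 20, 8 adjusted over the list alone, median 0.21, adjusted p = 1.57e-10) and hypoxia targets fell (6 of 23, 7 adjusted over the list alone, median -0.11, adjusted p = 1.86e-08). The glycolysis list was lower with the preset correlation (1 of 18, 5 lower and 1 higher adjusted over the list alone, adjusted p = 7e-06), with adjusted p = 0.1 with an estimated correlation. Of the 38 lists 16 were called, 9 of which held. In all 415 genes were called at the high dose (240 higher, 175 lower), 125 at the medium (104 higher, 21 lower) and 174 at the low dose (129 higher, 45 lower). Scaling by library size alone put 82.9%, 93.7% and 87% of the calls on the higher side, against 57.8%, 83.2% and 74.1%. Leaving out 1 library lowered the count to between 218 (without vehicle replicate 1) and 251 (without vehicle replicate 3) at the high dose. The medium dose gave 55 (without vehicle replicate 2) to 91 (without Rehmannia medium replicate 2), and the low dose 65 (without Rehmannia low replicate 1) to 101 (without vehicle replicate 3). Without Sagunja low library 1 the counts were 1336, 512 and 636, with 46.6%, 58.4% and 46.7% higher, and with only the groups compared they were 2456, 1788 and 1271, with 46.5%, 46.4% and 47.3% higher, so the excess of higher calls depended on the fit. With the low-dose groups as the reference 670 genes were called at the high dose. At the medium dose VIPR1 rose by 0.82 ± 0.13 (adjusted p = 0.000149), and at the low dose CXCL8 fell by 1.06 ± 0.14. CXCL8 also lay below vehicle at the low dose of Cnidium, Cinnamon, Astragalus and Samul, but not of Sagunja.

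Within the Rehmannia set 141 genes were called between the high and the low dose (78 higher, 63 lower). NPTX1 was higher at the high dose (1.40 ± 0.14, adjusted p = 8.7e-09), as were IGFBP1 (1.15 ± 0.12, adjusted p = 7.11e-09) and CXCL8 (1.42 ± 0.13, adjusted p = 2.03e-09), and the metallothionein gene MT1X was lower (-0.70). CXCL8 was at 5.26 CPM with Rehmannia low and 14 CPM with Rehmannia high, and vehicle libraries lay between these means, at 9.05 to 12 CPM. AHR targets were higher in 7 of 11 (8 adjusted over the list alone, adjusted p = 2.35e-29). The count was 74 without Rehmannia high replicate 2 and 94 without Rehmannia low replicate 1, and 612 without Sagunja low library 1, which brought the share of higher calls from 55.3% to 49%, and 809 with only these 2 groups in the fit.

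The Cnidium comparison asked what Cnidium rhizome does. Genes of the protein folding machinery of the endoplasmic reticulum fell at the high dose: HERPUD1 (ENSG00000051108, chromosome 16, 56932048 to 56944863) went from 123 ± 6.66 to 69.2 ± 1.22 CPM (-0.84 ± 0.06, adjusted p = 7.86e-14), and HSPA5, which encodes the chaperone BiP, from 3490 ± 104 to 2370 ± 66.7 CPM (-0.56 ± 0.05, adjusted p = 4.18e-09). HERPUD1 was at -0.42 against vehicle already at the Cnidium low dose, and lower at the low dose of every replicated extract. It was at 68 to 70.5 CPM with Cnidium high and 87.6 to 95 CPM with Cnidium low. The metallothionein genes MT1E (-1.10 ± 0.12, adjusted p = 8.77e-08) and MT1X (-0.88 ± 0.10) fell as well. The potassium channel subunit gene KCNE4 rose from 8.34 to 13.9 CPM (0.73 ± 0.12, adjusted p = 0.000328), and DHX58, a gene of the cytosolic RNA sensing pathway, rose by 0.72 ± 0.10 (adjusted p = 7.07e-05). TNFRSF25, a death receptor gene, was 0.87 ± 0.15 higher than in vehicle. It was at -0.12 with the low-dose groups of all 6 replicated extracts as the reference, and it was 0.92 higher than vehicle at the Cnidium low dose too.

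Endoplasmic reticulum chaperones were lower in 10 of 19 genes with Cnidium high (13 adjusted over the list alone, median -0.24, adjusted p = 2.54e-35), metallothionein and zinc export genes in 3 of 7 (3 adjusted over the list alone, median -0.39, adjusted p = 4.31e-14) and TGF-beta and YAP targets in 4 of 20 (7 adjusted over the list alone, median -0.16, adjusted p = 1.01e-11). NRF2 targets were higher in 7 of 20 (12 adjusted over the list alone, median 0.18, adjusted p = 4.36e-13), among them the cystine transporter gene SLC7A11 (0.63 ± 0.12) and NQO1 (0.45 ± 0.11). Of the 38 lists 13 were called, 7 of which held with an estimated correlation. In all 237 genes were called at the high dose (149 higher, 88 lower), 52 at the medium (40 higher, 12 lower) and 67 at the low dose (52 higher, 15 lower). Scaling by library size alone put 82.9% and 91.1% of the calls at the high and medium dose on the higher side, against 62.9% and 76.9%. Leaving out any 1 of the 6 libraries lowered the count, to between 81 (without vehicle replicate 1) and 125 (without vehicle replicate 3) at the high dose. The medium dose gave 15 (without Cnidium medium replicate 1) to 25 (without vehicle replicate 3), and the low dose 21 (without Cnidium low replicate 3) to 42 (without Cnidium low replicate 1). Without Sagunja low library 1 the counts were 972, 239 and 312, with 48.9%, 53.6% and 57.7% higher, and with only the groups compared they were 2311, 836 and 698, with 45.9%, 48.3% and 50.1% higher, so the excess of higher calls depended on the fit. With the low-dose groups as the reference 382 genes were called at the high dose. HERPUD1 fell at the medium dose too (-0.57 ± 0.06, adjusted p = 1.75e-08), and at the low dose NEAT1 rose from 287 to 470 CPM (0.71 ± 0.10, adjusted p = 6.39e-05).

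Within the Cnidium set 40 genes were called between the high and the low dose (26 higher, 14 lower). KCNE4 was higher at the high dose (0.72 ± 0.12, adjusted p = 0.000614), and MT1E (-0.86 ± 0.12, adjusted p = 3.6e-05) and MT1X (-0.68 ± 0.10, adjusted p = 6.07e-05) were lower. NEAT1, higher than vehicle at the low dose, was lower at the high than at the low dose (332 against 470 CPM, -0.50 ± 0.10, adjusted p = 0.00968). Endoplasmic reticulum chaperones fell (3 of 19, 9 adjusted over the list alone, median -0.19, adjusted p = 8.11e-27) and NRF2 targets rose (3 of 20, 7 adjusted over the list alone, adjusted p = 1.44e-17), while the TGF-beta and YAP list was not called (0 of 20, median -0.05, adjusted p = 0.0915). The count was 11 without Cnidium low replicate 3 and 29 without Cnidium low replicate 1, and 167 without Sagunja low library 1, which brought the share of higher calls from 65% to 51.5%, and 336 with these 2 groups alone, of which 47.6% were higher.

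The Samul comparison asked what the Samul formula does, which combines Rehmannia, Paeonia, Cnidium and Angelica; here n = 2 per dose. At the high dose VIPR1 rose from 3.06 to 9.40 CPM (1.61 ± 0.13, adjusted p = 6.38e-11), NPTX1 from 4.54 to 12 CPM (1.40 ± 0.16, adjusted p = 6.53e-08) and IGFBP1 from 20.5 to 47.4 CPM (1.21 ± 0.13, adjusted p = 1.87e-08). These 3 genes also rose with Rehmannia high. TXNIP rose by 1.21 ± 0.11 and the early growth response gene EGR1 by 1.20 ± 0.13. The inhibitor of differentiation genes ID3 (-1.08 ± 0.10, adjusted p = 8.06e-10) and ID2 (-1.01) fell, as did the long noncoding RNA gene UCA1 (-2.03 ± 0.22, adjusted p = 2.22e-08) and SAMD11 (-1.17 ± 0.13, adjusted p = 3.19e-08).

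AHR targets were higher in 7 of 11 genes with Samul high and lower in 1 (8 and 1 adjusted over the list alone, median 0.45, adjusted p = 3.46e-11), NRF2 targets higher in 9 of 20 (11 higher and 1 lower adjusted over the list alone, median 0.33, adjusted p = 1.19e-08), and endoplasmic reticulum chaperones lower in 5 of 19 (7 adjusted over the list alone, median -0.17, adjusted p = 1.52e-08). TGF-beta and YAP targets were lower in 10 of 20 and higher in 1 (12 lower adjusted over the list alone, median -0.32, adjusted p = 1.23e-11). FOXO targets (3 of 16, 4 higher and 1 lower adjusted over the list alone, adjusted p = 0.00284) and histones (4 of 13, also 4 adjusted over the list alone, adjusted p = 0.048) were called higher with the preset correlation, at adjusted p = 0.293 and 0.0826 with an estimated correlation. Of the 38 lists 14 were called, 7 of which held. In all 724 genes were called at the high dose (400 higher, 324 lower), 306 at the medium (159 higher, 147 lower) and 459 at the low dose (245 higher, 214 lower). Scaling by library size alone put 79%, 71% and 72.3% of the calls on the higher side, against 55.2%, 52% and 53.4%. Leaving out any 1 of the 5 libraries lowered the count, to between 207 (without Samul high replicate 1) and 463 (without vehicle replicate 2) at the high dose. The medium dose gave 17 (without Samul medium replicate 1) to 154 (without vehicle replicate 2), and the low dose 68 (without Samul low replicate 1) to 241 (without vehicle replicate 3). Without Sagunja low library 1 the counts were 2336, 1981 and 2301, with 44.3%, 36.9% and 39.5% higher, and with only the groups compared they were 2227, 4658 and 4960, with 45.4%, 44.1% and 44.7% higher, so the side with more calls turned. With the low-dose groups as the reference 318 genes were called at the high dose. VIPR1 rose at the medium dose (0.78 ± 0.14, adjusted p = 0.00149), though with an adjusted p of 0.0525 without Samul medium replicate 2, and at the low dose NEAT1 rose from 287 to 622 CPM (1.11 ± 0.11, adjusted p = 1.05e-08).

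Within the Samul set 129 genes were called between the high and the low dose (75 higher, 54 lower; 58.1% higher, and 70.9% with library size alone). NPTX1 (1.49 ± 0.18, adjusted p = 8.99e-07), IGFBP1 (1.48 ± 0.15, adjusted p = 7.93e-09) and TXNIP (1.38 ± 0.13, adjusted p = 2.13e-09) were higher at the high dose, and ID3 (-1.05 ± 0.11, adjusted p = 1.32e-08) and SAMD11 (-1.22 ± 0.14, adjusted p = 1.17e-07) were lower. AHR targets were higher in 6 of 11 (8 adjusted over the list alone, median 0.46, adjusted p = 3.62e-26), while the TGF-beta and YAP list was not called (1 higher and 1 lower, median -0.07, adjusted p = 0.124). The count was 42 without Samul low replicate 2 and 59 without Samul high replicate 1, and 335 without Sagunja low library 1.

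**Figure D3:**
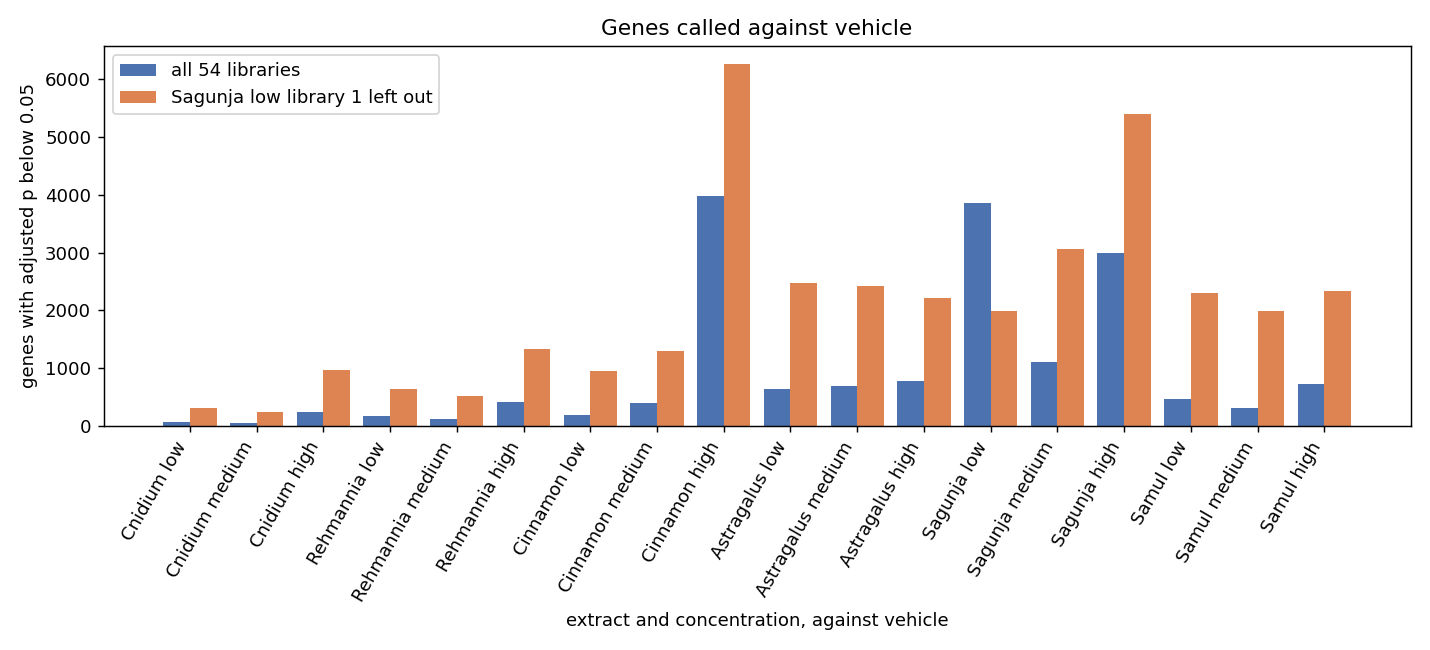
Number of genes called against vehicle (bars, vertical axis from 0) in the 18 groups of the 6 replicated extracts (horizontal axis), with all 54 libraries and with Sagunja low library 1 left out. With all libraries the counts ran from 52 for Cnidium medium to 3986 for Cinnamon high.

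3 pairs of extracts made in the same set were compared at the high dose, where no difference between sets enters. Cinnamon and Astragalus differed in 4838 genes (2377 higher with Cinnamon, 2461 lower), and in 7202 without Sagunja low library 1. INSIG1 was higher with Cinnamon (566 against 93.1 CPM, 2.60 ± 0.07, adjusted p = 2.54e-28), as was HMOX1 (4.05 ± 0.09, adjusted p = 1.71e-31), and SAMD11 was lower (17.4 against 99.4 CPM, -2.51 ± 0.12, adjusted p = 1.21e-20). Cholesterol synthesis genes were higher with Cinnamon in 20 of 22 (22 adjusted over the list alone, median 0.75, adjusted p = 5.18e-37) and AHR targets in 8 of 11 (8 adjusted over the list alone, median 1.45, adjusted p = 7.05e-26). Sagunja and Samul (n = 2) differed in 1464 genes (715 higher with Sagunja, 749 lower). CXCL8 was higher with Sagunja (420 against 14.1 CPM, 4.89 ± 0.15, adjusted p = 3.64e-26), VIPR1 was lower (1.62 against 9.40 CPM, -2.53 ± 0.14, adjusted p = 1.5e-17) and ITGB4 was lower (-1.75 ± 0.11, adjusted p = 1.83e-15). NF-kB targets were higher with Sagunja in 27 of 28 (also 27 adjusted over the list alone, median 2.00, adjusted p = 2.51e-271) and interferon response genes in 16 of 26 (22 adjusted over the list alone, median 0.61, adjusted p = 4.69e-20). The count of 1464 was 685 without Samul high replicate 2, 3067 without Sagunja low library 1 and 2389 with only these 2 groups in the fit.

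Cnidium and Rehmannia differed in 46 genes at the high dose (22 higher with Cnidium, 24 lower). The hypoxia-inducible genes BNIP3 (113 against 75.4 CPM, 0.59 ± 0.05, adjusted p = 1.34e-09) and DDIT4 (75.1 against 49.5 CPM, 0.60 ± 0.09, adjusted p = 0.000127) were higher with Cnidium. NPTX1 (5.56 against 13.5 CPM, -1.28 ± 0.14, adjusted p = 1.86e-07), VIPR1 (-0.94 ± 0.12, adjusted p = 2.92e-06) and SERPINB2 (32.2 against 59.6 CPM, -0.89 ± 0.07, adjusted p = 7.13e-12) were lower. AHR targets were lower with Cnidium (3 of 11, 6 adjusted over the list alone, median -0.45, adjusted p = 8.06e-37) and hypoxia targets higher (4 of 23, 12 adjusted over the list alone, median 0.24, adjusted p = 1.48e-31). The dose effect itself, high minus low, differed between Cnidium and Rehmannia in 7 genes, between Cinnamon and Astragalus in 2521 and between Sagunja and Samul in 506. With only the 4 groups concerned in the fit these counts were 60, 3138 and 12. Leaving out 1 library gave 3 to 7 genes for Cnidium and Rehmannia and up to 3924 for Sagunja and Samul. The count of 46 was 26 without Cnidium high replicate 2, 33 without Rehmannia high replicate 1, 147 without Sagunja low library 1 and 277 with only these 2 groups in the fit.

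Samul was compared with its parts by the correlation, across genes, of their changes from the low to the high dose. Genes are not independent replicates, so no p is given. Over 17516 genes Pearson's r was 0.25 with Rehmannia (Spearman's rho 0.32), 0.20 with Cnidium (rho 0.25), 0.18 with Paeonia (rho 0.31) and 0.08 with Angelica (rho 0.10), where Paeonia and Angelica had 1 library per dose. Among genes with a mean of at least 5 CPM it was 0.55, 0.44, 0.57 and 0.20 in the same order. With extracts that are not among its parts, r was 0.10 with Cinnamon and 0.10 with Astragalus, no lower than with Angelica, and -0.02 with Sagunja. Among genes with at least 5 CPM these were 0.21, 0.21 and -0.02. Cnidium and Rehmannia gave 0.20 (rho 0.28), and Cinnamon and Astragalus gave -0.12 (rho -0.17). Over all 28 pairs of extracts r ran from -0.12 to 0.25.

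Angelica and Paeonia had no replicates, so their values carry no test, and each vehicle library differed by at least 2-fold from the other 2 in 1 to 4 genes. With Paeonia high 16 genes differed at least 2-fold from the vehicle mean. NPTX1 was at 20.9 CPM against 4.58 (log2 ratio 1.98), TXNIP was higher by 1.60 and IGFBP1 by 1.28, while ID2 (-1.33), ID3 (-1.34), SAMD11 (-1.35) and MT1E (-1.35) were lower. The median log2 ratio of AHR targets was 0.65, that of NRF2 targets 0.25, that of hypoxia targets -0.38 and that of endoplasmic reticulum chaperones -0.27. With Angelica high 6 genes differed at least 2-fold. TXNIP was at 51.6 CPM against 9.62 (log2 ratio 2.31), its relative ARRDC4 was higher by 0.81 and MT1E was lower (-1.11), while endoplasmic reticulum chaperones were at -0.27. The medium and low doses gave 11 and 5 genes with Angelica and 4 and 3 with Paeonia. NEAT1 was higher by 0.74 with Angelica medium, by 0.81 with Angelica low and by 0.89 with Paeonia low.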

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

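The tests of a difference between dose effects were planned, and these results were singled out by a rule fixed beforehand. All 3 tests on the NF-kB genes were chosen only after the result was seen.

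The effect of the high against the low dose differed between Cinnamon and Astragalus in 2521 genes, between Sagunja and Samul in 506 and between Cnidium and Rehmannia in 7. HMOX1 rose with dose more under Cinnamon (4.10) than under Astragalus (0.37), a difference of 3.73 ± 0.12 (adjusted p = 1.87e-25). INSIG1 went up with Cinnamon (1.87) and down with Astragalus (-0.61), a difference of 2.48 ± 0.10 (adjusted p = 2.37e-22). FBXO32, a ubiquitin ligase gene of muscle wasting, did the same (1.10 and -0.41), a difference of 1.51 ± 0.07 (adjusted p = 1.64e-20). CXCL8 (4.37 with Sagunja), the adhesion molecule gene ICAM1 (1.89 with Sagunja and 0.15 with Samul) and SERPINB2 (2.39 and 0.82) rose more with dose under Sagunja than under Samul, by 3.12 ± 0.20 (adjusted p = 1.62e-14), 1.74 ± 0.11 (adjusted p = 1.62e-14) and 1.57 ± 0.11 (adjusted p = 4.49e-14). SERPINB2 rose with Rehmannia (0.82) but not with Cnidium (-0.17), a difference of -0.98 ± 0.10 (adjusted p = 1.5e-08). BNIP3 was at 0.01 with Cnidium and -0.57 with Rehmannia, a difference of 0.58 ± 0.08 (adjusted p = 3.36e-05). STC2 was at 0.06 and 0.49, a difference of -0.43 ± 0.06 (adjusted p = 0.000108), which was no longer called with no low-count filter. Leaving out 1 library gave 3 (without Rehmannia low replicate 1) to 7 genes for Cnidium and Rehmannia, and 203 (without Samul low replicate 2) to 3924 (without Sagunja low replicate 3) for Sagunja and Samul. With only the 4 groups concerned in the fit, Cnidium and Rehmannia gave 60 genes and the highest of the 49 other splits 5, and Cinnamon and Astragalus gave 3138 and the highest of the others 2, while Sagunja and Samul gave 12 and no other splits were tried. Where splits were tried, the real one alone (1 of 50) gave as many genes. These splits mixed the libraries of all 4 groups, so they also undid the differences between extracts and between doses. They therefore cannot tell a difference in dose effect from those other differences.

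Targets of NF-kB were higher with Sagunja at all 3 doses, with list medians of 0.59, 1.39 and 2.43. Samul high, of the same set, had a list median of -0.02 against the same vehicle, which argues against a difference between the sets of libraries. RNA from blood or microglial cells has no source in the design, as all samples came from an established cell line. The markers alone cannot decide it: 0 of the 4 measured were called higher against vehicle, but 11 were listed. CD68 was at 161 CPM in vehicle already, which would hide a small share. Against the low dose CD68 was called higher (0.39 ± 0.13, adjusted p = 0.0267). A response to something in the Sagunja extract that grows with dose is consistent with the medians, up to 2.43 at the high dose. Which substance it is, a plant compound or bacterial material in the preparation, was not tested.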

How the results depend on the processing

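2 alternatives, leaving Sagunja low library 1 out of every fit and a robust dispersion estimate, were chosen after seeing the data; the others were planned. No count of genes was moved beyond 1.5 times by DESeq2's size factors, by a minimum mean of 5 CPM or by the robust dispersion estimate, and the last ended no call of a named gene. Of 468 results for named genes, DESeq2's size factors ended the call of 3, library size alone 24, no low-count filter 29, the DESeq2 Wald test 1, fits of only the groups compared 28, Sagunja low library 1 out of every fit 6, and leaving out 1 library 121. A replicate term within the set ended 1 of 99 and a minimum mean of 5 CPM 2 of 388. Library size alone moved the median of all genes by up to 0.07. A replicate term ended no call of a named gene and 7 of 336 list calls, among them interferon response genes in Rehmannia high (adjusted p = 0.0537), oxidative phosphorylation in Cinnamon high (adjusted p = 0.0591) and collagens in Samul high (adjusted p = 0.0535). The robust quasi-likelihood step could not be fitted with no low-count filter, so its plain form was used there. Where leaving out a library left a Samul group with 1, that sample was assumed to vary like the other groups. Total counts of 20604792 to 29609799 limit what can be said of genes below the filter. With 2 or 3 libraries edgeR called 64% to 66% of 1.5-fold changes in the self-test. Except where fewer libraries, a different pool of libraries or more genes tested is the alternative's own construction, the cause was not tested.

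Without Sagunja low library 1 the counts against vehicle for the high, medium and low dose were 972, 239 and 312 for Cnidium, 1336, 512 and 636 for Rehmannia, 6265, 1297 and 952 for Cinnamon, 2214, 2419 and 2467 for Astragalus, 5400, 3065 and 1997 for Sagunja, and 2336, 1981 and 2301 for Samul. High against low gave 167 for Cnidium, 612 for Rehmannia, 6271 for Cinnamon, 203 for Astragalus, 1133 for Sagunja and 335 for Samul. The pairs gave 147 for Cnidium and Rehmannia and 3067 for Sagunja and Samul, and the tests between dose effects 33 for Cnidium and Rehmannia and 4855 for Cinnamon and Astragalus. It ended 15 list calls and turned 3: cytosolic ribosomal proteins in Sagunja low against vehicle (adjusted p = 0.000134 the other way) and in Sagunja high against low (adjusted p = 0.441), and oxidative phosphorylation in Sagunja high against low (adjusted p = 0.224).

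With only the groups compared in the fit the counts against vehicle were 2311, 836 and 698 for Cnidium, 2456, 1788 and 1271 for Rehmannia, 6094, 1170 and 453 for Cinnamon, 3054 and 4186 for Astragalus medium and low, 6477, 2083 and 0 for Sagunja, and 2227, 4658 and 4960 for Samul. For Sagunja low, 887 genes had an unadjusted p under 0.05 in this edgeR fit, and DESeq2 with all groups called 4025. High against low gave 336 for Cnidium, 809 for Rehmannia, 13 for Astragalus and 22 for Sagunja, the pairs 277 for Cnidium and Rehmannia and 2389 for Sagunja and Samul, and the tests between dose effects 60 for Cnidium and Rehmannia and 12 for Sagunja and Samul.

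With the mean of the low-dose groups of all replicated extracts as the reference, the high dose gave 382 genes for Cnidium, 670 for Rehmannia, 256 for Astragalus and 318 for Samul. It ended 67 calls of named genes. TNFRSF25 turned to -0.12 for Cnidium high and -0.06 for Astragalus high, CCN2 to 0.03 for Cnidium high and 0.10 for Rehmannia high, and LIF to 0.02 for Astragalus high. With no low-count filter the counts were 116 and 131 for Cnidium medium and low, 206 for Rehmannia medium, 106, 222 and 106 for high against low of Cnidium, Rehmannia and Astragalus, 102 for Cnidium against Rehmannia, and 69 and 1551 for the tests between dose effects of Cnidium and Rehmannia and of Sagunja and Samul. The DESeq2 Wald test gave 83 for Cnidium medium, 299 for Cinnamon low, 549 for Samul medium, 82 for Astragalus high against low and 73 for Cnidium against Rehmannia. A replicate term gave 490 for Samul medium, a replicate term within the set 71 for Cnidium against Rehmannia, and library size alone 31 for Astragalus high against low.

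An estimated correlation lowered the list calls from 204 to 112 against vehicle, from 85 to 53 for high against low and from 47 to 31 between extracts. Correlations of dose effects among genes with at least 5 CPM were 0.55 for Samul and Rehmannia, 0.44 for Samul and Cnidium, 0.20 for Samul and Angelica, 0.57 for Samul and Paeonia and 0.47 for Cnidium and Rehmannia. Among genes called between the high and low dose of either extract they were 0.81, 0.60, 0.64, 0.89 and 0.58, and -0.25 for Cinnamon and Astragalus. Angelica and Paeonia had no calls, so their values rest on the genes called in Samul. These genes were picked by their dose effects in the same libraries, which can itself enlarge r. Such values are therefore no independent measure of likeness. A pseudocount of 5 lowered the 2-fold genes to 3 and 1 for Angelica high and low and to 10, 2 and 1 for Paeonia high, medium and low.

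Leaving out 1 library at a time moved 124 of 190 counts. Against vehicle the ranges for the high, medium and low dose were 81 to 125, 15 to 25 and 21 to 42 for Cnidium, 218 to 251, 55 to 91 and 65 to 101 for Rehmannia, 3062 to 3305, 189 to 430 and 82 to 259 for Cinnamon, 405 to 920, 278 to 534 and 241 to 442 for Astragalus, 2024 to 2300, 571 to 996 and 1997 to 6977 for Sagunja, and 207 to 463, 17 to 154 and 68 to 241 for Samul. For high against low they were 11 to 29 for Cnidium, 74 to 94 for Rehmannia, 2918 to 3109 for Cinnamon, 22 to 35 for Astragalus, 1133 to 7487 for Sagunja and 42 to 59 for Samul. Between extracts they were 26 to 33 for Cnidium and Rehmannia, 3773 to 4569 for Cinnamon and Astragalus and 685 to 1192 for Sagunja and Samul, and for the tests between dose effects 3 to 7, 1868 to 2657 and 203 to 3924. Correlations of dose effects ran from 0.20 to 0.25 for Samul and Rehmannia, 0.14 to 0.21 with Cnidium, 0.05 to 0.09 with Angelica, 0.13 to 0.17 with Paeonia, 0.16 to 0.21 for Cnidium and Rehmannia, and -0.16 to -0.03 for Cinnamon and Astragalus.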

Other observations

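Of the tests here, those of a transcript length bias and of vehicle libraries made apart were chosen only after the result was seen, as were the comparison with other libraries' correlations and the simulation of a shared vehicle.

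At the low dose the 6 replicated extracts shared a set of changes from vehicle. NEAT1, the noncoding RNA that builds nuclear paraspeckles, rose by 0.71 to 1.11, the death receptor gene TNFRSF25 by 0.86 to 1.12 and the orphan nuclear receptor gene NR6A1 by 0.77 to 0.91. In all 35 genes were called higher with every extract. The 7 called lower with every extract were HERPUD1, the cyclin gene CCND1, the growth factor gene HBEGF, CCN2, the plasminogen activator gene PLAU, LIF and MAFF, with CCN2 between -0.54 and -0.70. These extracts have the vehicle libraries in common. In 4 simulations with no change but a shared vehicle, 0 genes were called by all 6 with edgeR, and the lowest and highest correlation between extracts were 0.403 and 0.537 on average, against 0.356 and 0.614 measured. The highest of any simulation was 0.566. The mean covariance was 0.0929, against 0.0615 on average and at most 0.0643 in the simulations. The vehicle libraries are too few to be divided between extracts. In the simulations each extract had 0 calls, so the 0 shared calls had to follow. They held no difference in set or solvent between vehicle and extract libraries. They therefore cannot tell such a difference from a response shared by the extracts.

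Targets of TGF-beta and YAP, such as CCN2, PLAU and HBEGF, lay below vehicle at the low dose of all 6 extracts, with list medians of -0.15 to -0.28. Chance values of the shared vehicle libraries are argued against: the list mean was -0.24, and the lowest of 10000 draws from the scatter within groups was -0.13 (a share of draws of 1e-04, the smallest they can give). With a trend over gene length and GC content removed, the mean of the 6 medians stayed at -0.22, with an SD of 0.05. Vehicle libraries made apart from the extract libraries cannot be told apart from a response shared by the extracts. The median was below 0 in 18 of 18 groups, as either would give. The sample titles name batch B for all libraries, but vehicle and extracts carry different set codes. The solvent cannot be told apart either, as the labels give a DMSO level for the vehicle only. A response to any added plant extract stays open as a hypothesis.

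Sagunja low library 1 differed from its replicates far more than any of the other 53 libraries did from theirs, with an SD of the deviation of 0.908 against 0.169 to 0.319. A transcript length bias is a candidate explanation: its deviation had a Spearman correlation of -0.53 with transcript length, against -0.39 to 0.36 in the others. The reference for this test was changed after a first outcome, so that replicates of this library were not measured against it. Its share of antisense transcripts was 0.53% against 0.27% to 0.30%, and its NF-kB genes were at a mean log2 CPM of 2.90, near 3.16 and 3.14 in its replicates and above vehicle (2.51 to 2.59). A mislabelled sample stays open, as the correlations with the 19 groups cannot decide it. Its own group ranked 7 among them, at 0.04, but no group came above 0.13. The other libraries had a median correlation of 0.38 with their own group and a lowest one of -0.10.

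With only the groups compared in the fit, all divisions of 3 libraries and 3 into 2 groups were counted. 10 splits are too few for a share under 0.05. Against vehicle, the real split and the highest other gave 2311 and 1 genes for Cnidium high, 836 and 3 for medium, 698 and 3 for low, 2456 and 3 for Rehmannia high, 1788 and 1 for medium, and 1271 and 3 for low. The numbers were 6094 and 0 for Cinnamon high, 1170 and 1 for medium, 453 and 2 for low, 873 and 1 for Astragalus high, 3054 and 1 for medium, 4186 and 1 for low, 6477 and 0 for Sagunja high, and 2083 and 2 for medium. For Sagunja low all 10 splits gave 0 genes with edgeR, the real one with 887 genes at an unadjusted p under 0.05, and DESeq2 with all groups called 4025. For high against low they were 336 and 3 for Cnidium, 809 and 2 for Rehmannia, 4547 and 1 for Cinnamon, 13 and 2 for Astragalus and 22 and 0 for Sagunja, and between extracts 277 and 2 for Cnidium and Rehmannia and 4627 and 0 for Cinnamon and Astragalus. In each but Sagunja low, 1 of the 10 splits, the real one, gave as many genes.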
